A study of Mus musculus with 28 samples.

How the data were processed

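The series measured DNA copy number by exome sequencing in mouse tumours. An exome library holds the captured protein-coding parts of the genome, so copy number is sampled at the capture targets and not between them. DNA came from 24 tumours and from 4 ear samples labelled as normal controls, 28 samples in all, read at 150 nt. The mice carried a germline change of p53, the tumour suppressor encoded by Trp53, which binds DNA as a tetramer. Per the labels, AD animals had an allele for a dimeric form of the protein and RP animals an allele for a monomeric form, in each case opposite a null allele. Both genotypes were on a mixed background of BALB/C and C57BL6, and tumours were taken when the animals reached their end point. Groups were read from the genotype and tissue labels: 7 AD and 7 RP thymic lymphomas, and 5 AD and 5 RP sarcomas. Each tumour is 1 replicate, and replicates are numbered in the order of the labels.

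The deposited files hold 1 table of copy number segments per tumour. The submitters' processing notes name Trim Galore 0.6.5, BWA 0.7.17, GATK 4.1.0.0 and the mouse build GRCm38, without their order or roles. Per the file headers, each segment has a chromosome, a start, an end, a number of markers and a segment mean. The segment mean in the deposited files is a mean log2 copy ratio, the tumour signal over that of a comparison DNA. The number of markers in the deposited files counts capture targets or windows, not reads. Which DNA each tumour was compared with, the settings of the segmentation, the centring and any correction for normal cells are not given in the sources used here. Normal cells in a tumour pull every log2 value towards 0. A germline difference shared with the comparison DNA leaves no trace in the ratio, and one that is not shared looks like a gain or a loss. A noisy library is broken into more short segments. Read depth is unknown, so no interval or limit based on counts is given, and the 24 tumours are the only measure of error.

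The 24 tables held 3727 segments, with at least 2 markers in each, and 0 pairs of tables were identical. The log scale was read from the negative values, and base 2 was checked on chromosome X, which does not settle it alone. Over the 24 tumours its mean ran from -0.91 to 1.88. AD sarcomas 1, 2 and 4 had -0.80, -0.91 and -0.91, near the -1 that 1 copy against 2 gives on a log2 scale. RP thymic lymphomas 4, 5, 6 and 7 had 1.88, 1.15, 1.14 and 1.38, above the 1 that 2 copies against 1 gives. RP thymic lymphoma 4 came from an animal whose ear was also sequenced, and a comparison with that ear is not established. Autosomal marker totals separated the groups without overlap. They were 204845 to 204849 in AD thymic lymphomas and 204917 to 204922 in RP thymic lymphomas, and 205075 to 205076 in AD sarcomas and 205073 to 205074 in RP sarcomas. Totals do not show which markers differ, and the gap of 1 marker between AD and RP sarcomas is as small as the spread within each. The totals also separate thymic lymphomas from sarcomas. If groups with other totals were processed apart, that processing cannot be told apart from genotype in thymic lymphomas, or from tumour type. In each group, 1 tumour came from an animal whose ear was also sequenced.

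Autosomes were analysed, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A segment was called gained at a log2 copy ratio of 0.3 or above and lost at -0.3 or below. The altered genome is the percent of the segmented autosomal length in such segments. An autosome was called changed as a whole when at least 80% of its segmented length was gained, or at least 80% lost. Means per autosome weighted each segment by its length. Bins of 1 Mb were used where a segment reached the bin in every tumour, which left 2388 bins. A gene took the mean of the segments that overlap it, weighted by overlap, or the value of the nearest segment where none did. Gene positions came from the RefSeq annotation of GRCm38.p6, which is the build of the files; the table used has no exons, so values are given for whole genes. The 8 gene lists held 232 symbols, of which 231 were matched by symbol and 1 by synonym; 227 lie on autosomes and were tested, and 5 lie on chromosome X. A list was scored by the percent of its genes altered in each tumour.

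Means of AD and RP tumours were compared with two-sided exact permutation tests over all 3432 splits of 7 against 7 tumours, where the smallest p is 0.000583, or all 252 splits of 5 against 5, where it is 0.00794. Thymic lymphomas and sarcomas were compared with two-sided permutation tests of 100000 resamples within genotype, where the smallest p is 1e-05. Genes and antigen receptor loci were compared with two-sided Fisher's exact tests on the number of altered tumours. Gains and losses of a gene counted as separate tests, so 454 tests of the 227 genes were adjusted together. The Benjamini-Hochberg method adjusted over autosomes, bins, genes, lists or loci, each as its own family, with 0.05 as the threshold. Bins were also tested with limma 3.58.1 in R 4.3.3 as another tool. Neighbouring bins, and genes on 1 segment, are not independent.

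The groups, tests, lists, cutoffs and alternatives were fixed before the data were examined, except where an alternative is said to be chosen after seeing the data. So was the rule for the genes named. It takes Trp53 in every tumour, and listed genes gained or lost in at least 3 tumours of a group or 4 of a tumour type, up to 30 per comparison, ranked by altered tumours and then by mean absolute log2. It adds listed genes in a focal segment, meaning at most 5 Mb long with a log2 copy ratio at or beyond 1 or -1. It then takes for each comparison of AD with RP the 5 separate bins with the largest difference of means. Of the 227 genes, 121 met the first part, and the first 30 were kept. Some listed genes are not reported here by name; they stay in the counts of genes and lists, and were left out of the search for single values that stand apart. The alternatives were cutoffs of 0.2 and 0.5 and a linear copy ratio outside 0.9 to 1.1, centring each tumour on its own length-weighted median, leaving out segments under 1 Mb, weighting by markers, ranks, 5 Mb bins, shares of 60% and 95% for a whole autosome, joining neighbouring segments in the same state, adding chromosome X, limma, leaving out the 4 tumours with a sequenced ear, and leaving out each tumour in turn.

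The tests were tested on simulated data, made from the real tables by removing each group's mean and adding known shifts to some bins or autosomes. Most added shifts were found in thymic lymphomas and between tumour types. All of them were larger than the AD minus RP difference of any autosome in thymic lymphomas, at most -0.32, for chromosome 14. Power to find differences of that size was therefore not simulated. In sarcomas, a small set of shifted bins was missed, since at 5 against 5 tumours at least 380 bins must reach the smallest p together for any to pass. In the same simulation no listed gene passed in sarcomas, even when lost in all 5 tumours of 1 genotype. Chromosomes X and Y were left out of the comparisons, since the sexes of the animals are not given in the sources used here. The reads and the ear samples were not analysed here. No paired analysis was made, because the labels give animal numbers and no shared replicate numbers between groups.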

Results

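Copy number profiles were measured in 24 tumours of mice that carried a mutant p53 allele opposite a null allele. The mutant protein was dimeric in AD animals and monomeric in RP animals. The tumours were 7 AD and 7 RP thymic lymphomas, which are T-cell tumours of the thymus, and 5 AD and 5 RP sarcomas, which are tumours of connective tissue. Values are log2 copy ratios of a tumour over a comparison DNA, as mean ± SD over tumours, with positions on GRCm38. Each tumour had between 211948 and 212450 markers in 59 to 517 segments, and the read depth behind them is unknown. The labels name 1 question, how genomic alterations compare between dimeric and monomeric p53 in each tumour type.

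Trp53, the engineered gene at chromosome 11, 69580348 to 69591873, was called lost in 0 of the 24 tumours. Its mean log2 copy ratio was 0.04 ± 0.12 in AD thymic lymphomas (n = 7), 0.04 ± 0.22 in RP thymic lymphomas (n = 7), 0.08 ± 0.07 in AD sarcomas (n = 5) and 0.08 ± 0.06 in RP sarcomas (n = 5). The gene was called gained in 1 tumour, RP thymic lymphoma 5, at 0.36. That value came from a short segment inside the gene, 69586890 to 69588625, with 5 markers and a log2 of 0.68. A segment with the same ends stood at 0.63 in RP thymic lymphoma 7, at -0.33 in RP thymic lymphoma 1 and at -0.31 in AD thymic lymphoma 5. At a cutoff of 0.2 it was called lost in 1 tumour. The germline null allele leaves no trace in these ratios if the comparison DNA carries it too.

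In thymic lymphomas, AD and RP tumours shared called losses of chromosomes 13, 18 and 19 and gains of chromosome 4. Chromosome 13 was lost as a whole in 4 of 7 AD and 5 of 7 RP tumours, chromosome 18 in 4 and 4, and chromosome 19 in 3 and 5. These calls used uncentred values, and the length-weighted median log2 of thymic lymphomas was -0.12 ± 0.07, which makes a loss easier to call. With centring, chromosomes 18 and 19 did not pass against sarcomas (permutation test within genotype, adjusted p = 0.33 and 0.0662). Chromosome 4 was gained as a whole in 2 AD and 4 RP tumours. Chromosome 15, which carries the oncogene Myc, was gained as a whole in 1 AD and 4 RP tumours, with means of 0.14 ± 0.23 and 0.40 ± 0.19. Chromosome 5 was gained as a whole in 3 AD and 0 RP tumours, with means of 0.28 ± 0.15 and 0.07 ± 0.13. Chromosome 14 had means of 0.00 ± 0.39 in AD and 0.32 ± 0.23 in RP tumours, with whole gains in 2 and 4.

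None of these differences between AD and RP thymic lymphomas passed the adjusted exact permutation test. The largest unadjusted signals were chromosome 5 (difference 0.21, exact p = 0.0198, adjusted p = 0.334, n = 7 each) and chromosome 15 (difference -0.25, exact p = 0.0367, adjusted p = 0.334). Chromosome 14 differed by -0.32 (exact p = 0.088). So 0 of 19 autosomes passed. Of the 2388 bins of 1 Mb, 0 passed the exact permutation test, where 236 had an unadjusted p under 0.05 and the smallest adjusted p was 0.417. With limma, 0 bins passed and 284 had an unadjusted p under 0.05.

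**Figure D1:**
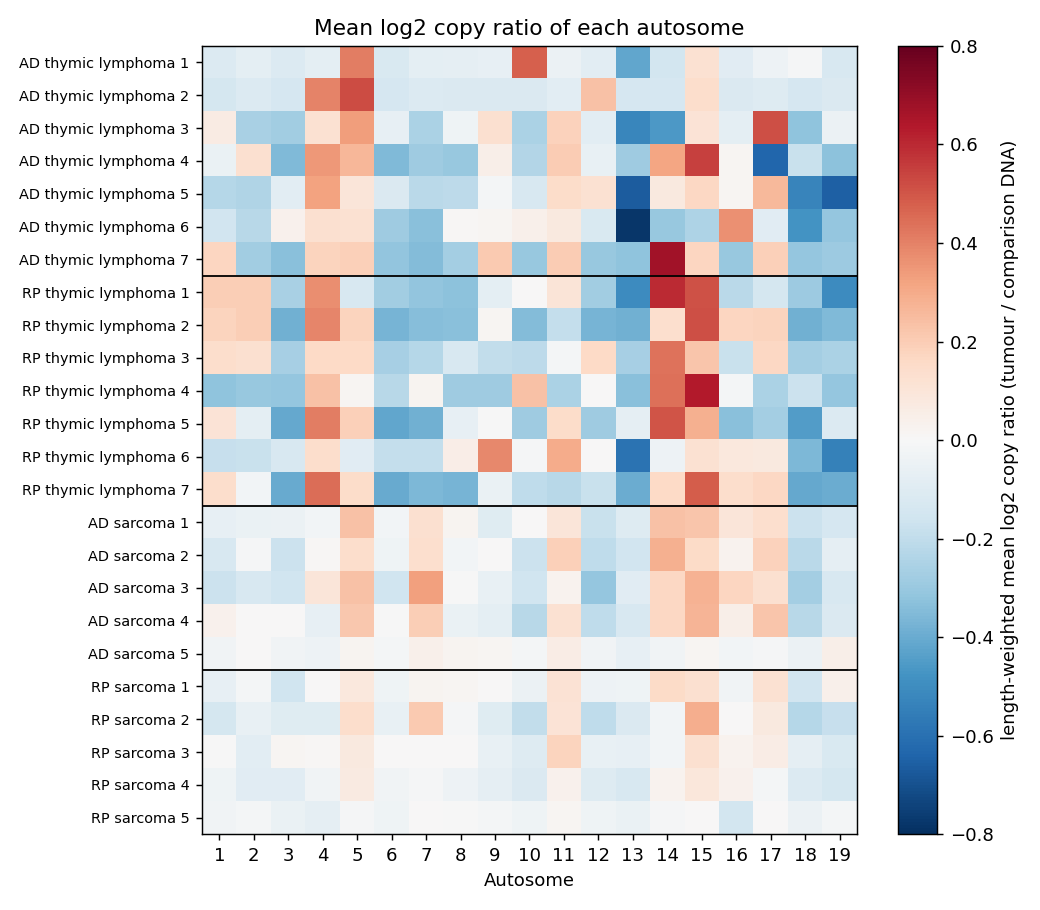
Length-weighted mean log2 copy ratio of each autosome (columns) in each tumour (lines of cells), with red for gain and blue for loss on a scale of -0.8 to 0.8. Thymic lymphomas, in the upper 14 lines, show loss of chromosome 13 (mean -0.40) and gain of chromosome 4 (mean 0.25), while the 10 sarcomas lie nearer 0 (means -0.09 and -0.02).

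Amplification of Mycn and Akt1 was found in AD thymic lymphomas 5 and 6 and in 0 RP thymic lymphomas. Mycn, an oncogene of the Myc family at chromosome 12, 12936093 to 12941836, lay in focal segments at 6.33 and 6.40, which are 80.6 and 84.7 times the ratio of the comparison DNA. Akt1, a kinase of PI3 kinase signalling on the same chromosome, stood at 1.17 and 4.80. Myc was amplified at 1.35 in RP thymic lymphoma 4. Gain of Mycn in 2 AD against 0 RP thymic lymphomas gave a Fisher's exact p of 0.462. Short losses of at most 4 markers touched the apoptosis gene Bbc3 (-1.17), the lipase gene Pnpla2 (-1.53) and the phosphatase gene Ptpn2 (-2.06) in AD thymic lymphoma 7. That tumour and AD thymic lymphoma 6 had 169 and 93 losses of at most 10 markers and 50 kb, against 11 to 19 in the RP thymic lymphomas.

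The 5 separate bins with the largest difference between AD and RP thymic lymphomas were led by these amplified regions. The bin with Mycn, chromosome 12, 12000001 to 13000000, had means of 1.002 ± 2.41 in AD and -0.13 ± 0.20 in RP tumours (difference 1.13, exact permutation p = 0.118, n = 7 each). Its neighbours in rank on chromosome 12 were the bin of Akt1 (difference 0.75, AD SD 1.62), the bin of Twist1 from 33000001 (0.61, AD SD 1.37) and the bin of Gphn from 78000001 (0.55, AD SD 1.32). These 4 differences rest on AD thymic lymphoma 6, and without it they were 0.23 for Mycn, 0.14 for Akt1, 0.09 for Twist1 and 0.06 for Gphn. The bin over the T-cell receptor beta genes, chromosome 6, 41000001 to 42000000, had means of -0.67 ± 0.56 in AD and -1.52 ± 0.51 in RP tumours (difference 0.85, exact permutation p = 0.0146, adjusted p = 0.417, n = 7 each).

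Across the 8 gene lists, 0 lists and 0 of the 227 genes differed between AD and RP thymic lymphomas. By Fisher's exact test 0 genes had an unadjusted p under 0.05, and the count adjusted over the list alone was also 0 for each list. The 48 genes of lipid and energy metabolism were altered in 21.1% ± 11.5 of cases in AD and 36.6% ± 21.5 in RP tumours (exact permutation p = 0.128, adjusted p = 0.417, n = 7 each). Among them the desaturase gene Scd1 was lost in 3 AD and 5 RP tumours, the kinase gene Pdk4 in 2 and 5, and the coactivator gene Ppargc1b in 4 and 4. Glucose transporter gene Slc2a1 was gained in 3 and 4, Aldh4a1 in 3 and 5, Cpt2 in 3 and 4, and Pck2 in 2 and 4, while 1 AD tumour each had Pck2 lost and Pdk4 gained.

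In the p53 pathway list, 22.7% ± 9.82 of the 22 genes were altered in AD and 31.2% ± 19 in RP thymic lymphomas (exact permutation p = 0.365, n = 7 each). The p53 relative Trp73 was gained in 4 AD and 5 RP tumours, Sesn2, a stress response gene, in 3 and 5, and the apoptosis gene Pmaip1 was lost in 4 and 4. At a cutoff of 0.5 this list was the only 1 of 8 to differ, with 5.19% in AD and 0% in RP tumours (exact permutation adjusted p = 0.0373, n = 7 each). That rests on 8 values in 6 AD tumours. Some lay near the cutoff: Cdkn1a at 0.52 in AD thymic lymphoma 3, and Pmaip1 at -0.53 and -0.54 in 5 and 6. Others lay further out: Cdkn1a at -0.88 in AD thymic lymphoma 2, and the rest at 0.85 in 2 and -0.82 in 4, the last being the same value for more than 1 gene. Bbc3 in 7, at -0.94 over the whole gene, rests on the 4-marker loss. In RP thymic lymphoma 1, Sesn2 at 0.4999 fell just short. A higher AD share at this cutoff was not particular to the p53 list. The AD minus RP difference was 6.30 points for receptor kinase and growth signalling genes, 5.49 for cell cycle genes and 5.26 for sarcoma genes. Each of these had an adjusted p of 0.136 by exact permutation test. Only chromatin regulators went the other way (-2.60 points). The 52 T-cell lymphoma genes had 21.4% ± 12.1 and 29.7% ± 16.3 altered (exact permutation p = 0.313, n = 7 each), among them Rpl22, gained in 4 and 5, Tal1, gained in 3 and 4, Hhex, lost in 3 and 5, and Ptpn2, lost in 4 and 4.

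Receptor kinase and growth signalling genes, 34 in number, were altered in 28.2% ± 7.57 and 33.2% ± 18.6 (exact permutation p = 0.567, n = 7 each). Here Pik3r1 and Fgfr4 were each lost in 5 and 5 AD and RP tumours, Pdgfrb was lost in 4 and 4, and Mtor was gained in 4 and 5. Met and Braf were each lost in 2 and 4 and gained in 1 AD tumour. The 38 sarcoma genes gave 26.3% ± 8.04 and 34.6% ± 18.8 (exact permutation p = 0.333, n = 7 each), with Ptch1 lost in 5 and 5 and Rb1 gained in 2 and 4 and lost in 1 AD tumour. The 26 cell cycle genes gave 24.2% ± 7.92 and 34.6% ± 23.3 (exact permutation p = 0.303, n = 7 each), with Ccnb1 lost in 5 and 5, E2f3 lost in 4 and 5, and Cdkn2c gained in 3 and 4. Genome maintenance genes, 29 in number, gave 15.3% ± 11.6 and 25.1% ± 12.5 (exact permutation p = 0.169, n = 7 each), with the telomerase gene Tert lost in 5 and 5. The 22 chromatin regulators gave 20.1% ± 15.9 and 33.1% ± 16.7 (exact permutation p = 0.18, n = 7 each), with Arid1a and Hdac1 each gained in 3 and 5, and Bap1 gained in 2 and 4 and lost in 2 AD tumours.

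The altered share of the autosomes was 26.0% ± 12.5 in AD and 34.8% ± 16.9 in RP thymic lymphomas, a difference of -8.82 points that was smaller than the spread between tumours (exact permutation p = 0.282, n = 7 each). Gained regions took 10.3% ± 5.39 and 10.5% ± 3.16, and lost regions 15.7% ± 11.5 and 24.2% ± 14.9 (exact permutation p = 0.252 for losses, n = 7 each). Whole-autosome changes numbered 4 ± 1.63 per AD and 6.29 ± 3.25 per RP tumour (exact permutation p = 0.151, n = 7 each), and altered segments 127 ± 90.6 and 66.7 ± 15.9 (exact permutation p = 0.123, n = 7 each). The difference in altered segments was 60.7, and over the alternatives it ran from 2.43 to 85.1 (exact permutation p from 0.0437 to 0.501). Joining neighbouring segments of 1 state changed the call for altered segments (difference 48.4, exact permutation p = 0.0437), and so did leaving out AD thymic lymphoma 1 (73.0) or 2 (73.8), while without AD thymic lymphoma 7 the difference was 33.0, and without AD thymic lymphomas 6 and 7, an alternative chosen after seeing the data, it was 15.1 (exact permutation p = 0.501). Altered segments of 1 Mb or longer numbered 30.3 and 25.0 (exact permutation p = 0.485), and shorter ones 97.1 and 41.7 (exact permutation p = 0.0653), with 157 and 246 of the shorter ones in AD thymic lymphomas 6 and 7. Requiring 95% of the length changed the call for whole autosomes (difference -2.71, exact permutation p = 0.0484), as did leaving out RP thymic lymphoma 3 (-3.17), and a cutoff of 0.5 turned the sign of the altered share (2.98 points) and of whole-autosome changes (0.429).

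**Figure D2:**
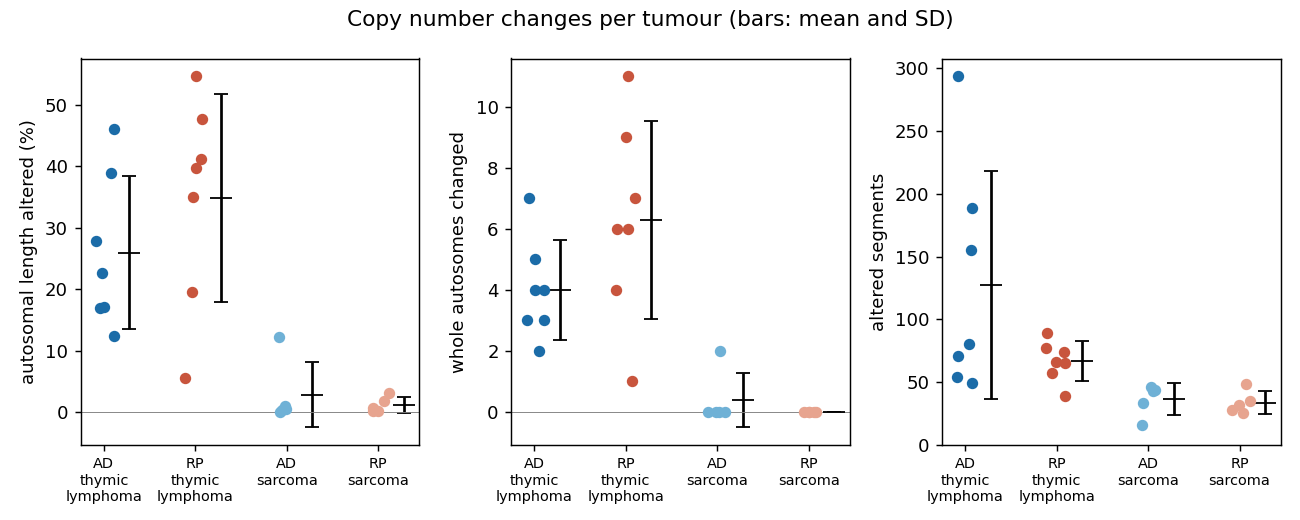
Percent of autosomal length altered, number of autosomes changed as a whole and number of altered segments in each tumour (points), with the mean and SD of each group in black. The 14 thymic lymphomas lie between 5.51% and 54.7% altered, and the 10 sarcomas between 0.012% and 12.2%.

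At the cutoff of 0.3, sarcomas of both genotypes had little of their autosomes altered, 0.012% to 3.14% in 9 tumours and 12.2% in AD sarcoma 3. Smaller shifts lay within it. Chromosome 15 stood at 0.16 ± 0.11, above 0 in 10 of 10 sarcomas, and chromosome 18 at -0.15 ± 0.08, below 0 in 10 of 10. Chromosome 11 (0.09 ± 0.06) was also above 0 in 10 of 10. Chromosomes 12 (-0.14 ± 0.10) and 13 (-0.09 ± 0.04) were below 0 in 10 of 10. Whether such shared shifts come from the tumours or from the comparison DNA was not tested. Normal cells pull values towards 0 and their share is not given, so low values need not mean few changes. Among listed oncogenes, AD sarcoma 1 had a focal gain at 1.39 at chromosome 5, 75162242 to 75946818, and 1 at Nras, at 1.11. The first covered the receptor kinase gene Kit, 76.7% of Pdgfra and 30.3% of Kdr. In RP sarcoma 2, Myc was amplified at 2.22, and the cyclin gene Ccne2 at 2.11. The Ccne2 segment was 10.3 kb long with 11 markers, lay inside the gene and covered 71.7% of it. A region of chromosome 2, 176706853 to 178032800, with 11 protein-coding genes named as zinc finger proteins or gene models, stood at 1.05 ± 0.12 in AD sarcomas 1 to 4 and at 0.01 in AD sarcoma 5. Whole autosomes changed in AD sarcoma 3 alone, with a gain of chromosome 7 and a loss of chromosome 12.

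No autosome, gene or list passed the adjusted tests between AD and RP sarcomas. With the exact permutation test 0 of 19 autosomes passed (smallest adjusted p = 0.422), and 0 of 2388 bins passed, where 142 had an unadjusted p under 0.05 and the smallest adjusted p was 0.607. With limma 0 bins passed, 341 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0706. By Fisher's exact test 0 of the 227 genes passed, and 0 had an unadjusted p under 0.05 or passed when adjusted over the list alone. The bin with the largest difference, chromosome 2, 176000001 to 177000000, had means of 0.84 ± 0.48 in AD and -0.04 ± 0.03 in RP sarcomas (difference 0.88, exact permutation p = 0.00794, n = 5 each, the smallest these tests can give). The others among the 5 were 2 bins of chromosome 16, from 17000001 (difference -0.55) and from 31000001 (-0.49), the bin of Myc on chromosome 15 (-0.34) and the bin of chromosome 4 from 153000001 (0.29). These 4 rest on 1 or 2 tumours. In the order given they were -0.16 without RP sarcoma 5, -0.26 without RP sarcoma 3 and -0.34 without RP sarcoma 5, 0.09 without RP sarcoma 2 and 0.14 without AD sarcoma 2.

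The altered share was 2.81% ± 5.28 in AD and 1.18% ± 1.31 in RP sarcomas, a difference of 1.63 points (exact permutation p = 0.825, n = 5 each) that turned to -0.72 without AD sarcoma 3. With a cutoff of 0.2 this difference was 10.98 points, and with a linear copy ratio outside 0.9 to 1.1 it was 21.2 points (exact permutation p = 0.135 and 0.167). Whole-autosome changes differed by 0.4 per tumour (exact permutation p = 1), and by 4.4 with the linear cutoff (exact permutation p = 0.143). Altered segments numbered 36.4 ± 12.5 and 33.6 ± 8.91 (exact permutation p = 0.738, n = 5 each). In AD and RP sarcomas, chromatin regulators were altered in 7.27% and 2.73%, receptor kinase and growth signalling genes in 5.29% and 0%, sarcoma genes in 4.74% and 1.05%, and lipid and energy metabolism genes in 3.75% and 1.25%. The p53 pathway list was altered in 3.64% and 0.909%, T-cell lymphoma genes in 3.46% and 1.15%, cell cycle genes in 2.31% and 1.54%, and genome maintenance genes in 2.07% and 0.69%. The smallest adjusted p of the exact permutation tests of these lists was 0.963.

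Thymic lymphomas differed from sarcomas in 8 of 19 autosomes. Chromosome 4 was higher in thymic lymphomas, at 0.25 ± 0.15 against -0.02 ± 0.06, and was above 0 in 13 of 14 thymic lymphomas. Chromosomes 3, 6, 7, 8, 13, 18 and 19 were lower. Without centring, chromosome 7 had the largest difference, with -0.24 ± 0.12 in thymic lymphomas (n = 14) against 0.11 ± 0.11 in sarcomas (n = 10), and was below 0 in 13 of 14 thymic lymphomas. Chromosome 13 stood at -0.40 ± 0.20 against -0.09 ± 0.04, and was below 0 in 14 of 14 thymic lymphomas and 10 of 10 sarcomas.

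These 8 autosomes, 1 higher and 7 lower, passed the permutation test within genotype (adjusted p = 0.00038 for chromosome 7, 0.00057 for chromosome 4 and 0.000617 for chromosome 13). Of the 2388 bins, 951 passed, with 141 higher and 810 lower, and limma gave 951. The length-weighted median log2 was -0.12 ± 0.07 in thymic lymphomas and -0.03 ± 0.03 in sarcomas (difference -0.09, permutation p = 0.00071). With each tumour centred on its median, 4 autosomes passed (4 higher, and 6, 7 and 13 lower), the largest difference was that of chromosome 4 (0.36, against -0.26 for chromosome 7), and 153 bins were higher and 288 lower. With 5 Mb bins 199 passed (30 higher and 169 lower). Autosomal marker totals also separate the tumour types, so a difference in processing between them is not excluded.

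Losses of 6 listed genes were more frequent in thymic lymphomas. Among them, Tert, Pik3r1, Ccnb1, Ptch1 and Fgfr4 on chromosome 13 were each lost in 10 of 14 thymic lymphomas and 0 of 10 sarcomas, with means in thymic lymphomas from -0.43 for Tert to -0.41 for Fgfr4. By Fisher's exact test each of these had an adjusted p of 0.0441 over all 454 tests, of which 56 had an unadjusted p under 0.05.

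The count adjusted over the list alone was the same as over all genes for 7 of the 8 lists. For receptor kinase and growth signalling genes it was 3 losses and 1 gain, against 3 losses over all genes. For p53 pathway, lipid and energy metabolism and chromatin regulator genes both counts were 0, though Trp73 was gained in 9 thymic lymphomas and 2 sarcomas, Sesn2 and Arid1a in 8 and 0, and Scd1 was lost in 8 and 0. E2f3 was lost in 9 and 0 and Mtor gained in 9 and 0 (adjusted p = 0.115 by Fisher's exact test for both). Rpl22 was gained in 9 and 2, Ccne2 in 7 and 1, and on chromosome 15 Sco2, Arid2 and Kmt2d in 5 and 3, and Xrcc6, Srebf2, Ep300 and Ppara in 5 and 2. The 6 calls depend on the cutoff and on single tumours: they numbered 0 at a cutoff of 0.5, with centring, without segments under 1 Mb and without most single tumours, and 73 at a cutoff of 0.2.

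All 8 lists had a larger share of altered genes in thymic lymphomas than in sarcomas. Receptor kinase and growth signalling genes showed the largest difference, with 30.7% against 2.65% (permutation test within genotype, adjusted p = 0.00028), and genome maintenance genes the smallest, with 20.2% against 1.38% (adjusted p = 0.000503). The other shares were 26.9% against 2.27% for the p53 pathway, 25.5% against 2.31% for T-cell lymphoma genes, 30.5% against 2.89% for sarcoma genes, 29.4% against 1.92% for cell cycle genes, 28.9% against 2.5% for lipid and energy metabolism genes and 26.6% against 5% for chromatin regulators, with adjusted p of at most 0.00206. The altered share of the autosomes was 30.4% ± 15.0 in thymic lymphomas and 1.99% ± 3.73 in sarcomas (difference 28.4 points, permutation p = 5e-05). The difference was 23.2 points in AD and 33.6 points in RP tumours (exact permutation p = 0.00379 in each). The share of normal cells in each tumour type is not given, and more of them would lower the altered share.

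The T-cell receptor loci, which T cells rearrange by deleting DNA between gene segments, each held a segment called lost in every thymic lymphoma. Such a call also counts loss of the whole chromosome. At Tcrg the shallowest value was -0.31, where chromosome 13 had a mean of -0.40. The Tcra/Tcrd locus, at chromosome 14, 52427967 to 54224198, had a segment at or below -0.3 in 14 of 14 thymic lymphomas and 1 of 10 sarcomas, and the mean of the lowest segment was -3.52 ± 0.94 against 0.01 ± 0.32. The call in that sarcoma, AD sarcoma 5, rests on a segment of 2 markers. The Tcrb locus on chromosome 6 was lost in 14 and 1 (mean lowest segment -3.22 ± 1.23 against -0.07 ± 0.10), and the Tcrg locus on chromosome 13 in 14 and 0 (-2.23 ± 1.56 against -0.09 ± 0.04). Of the antibody gene loci, Igh on chromosome 12 was lost in 13 and 1 (-1.68 ± 1.27 against -0.14 ± 0.10), Igk on chromosome 6 in 6 and 0, and Igl on chromosome 16 in 3 and 0.

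By Fisher's exact test 5 of the 6 loci passed, with adjusted p of 1.53e-05 for Tcra/Tcrd and Tcrb, 3.06e-06 for Tcrg, 0.000108 for Igh and 0.0286 for Igk, and 0.239 for Igl. Each of the 3 T-cell receptor loci was lost in 7 AD and 7 RP thymic lymphomas, so their counts leave nothing to test. The mean lowest segment of Tcrb was -2.74 ± 1.24 in AD and -3.71 ± 1.09 in RP thymic lymphomas (n = 7 each). Igh was lost in 6 AD and 7 RP thymic lymphomas, Igk in 3 and 3, and Igl in 2 and 1 (Fisher's exact p = 1 for each). Counting only segments at least 1 below the median of their own chromosome, an alternative chosen after seeing the data, gave 14 of 14 thymic lymphomas for Tcra/Tcrd, 13 for Tcrb, 7 for Tcrg, 9 for Igh and 0 for Igk, with 0 of 10 sarcomas at each. Without segments under 1 Mb, 3 loci passed.

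**Figure D3:**
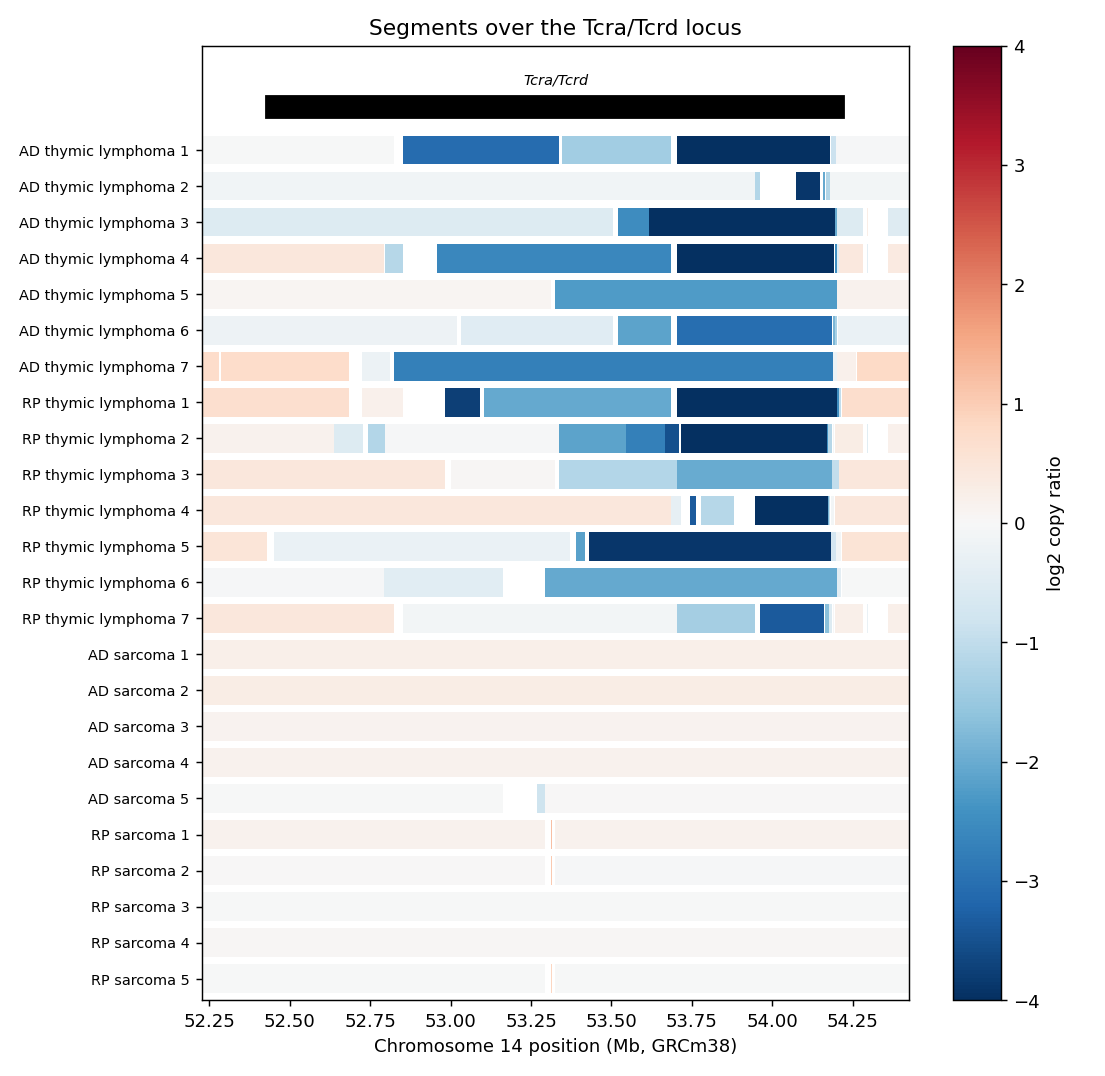
Segments over the Tcra/Tcrd locus on chromosome 14 (black bar) in all 24 tumours, coloured by log2 copy ratio from -4 to 4, with blank gaps where no segment was reported. All 14 thymic lymphomas have a loss inside the locus, with the lowest segment between -4.59 and -2.003, and the lowest segment of the sarcomas lies between -0.83 and 0.30.

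The difference between AD and RP tumours in the altered share of the autosomes was -8.82 points in thymic lymphomas and 1.63 points in sarcomas. The difference of these, -10.5 points, was not larger than permuting genotype within tumour type gives (permutation p = 0.217). With a linear copy ratio outside 0.9 to 1.1 it was -41.0 points (permutation p = 0.0272), from -19.8 in thymic lymphomas and 21.2 in sarcomas, and with a cutoff of 0.5 it was 2.96. Chromosomes 14 and 15 had the largest such differences in mean log2, at -0.46 (permutation p = 0.0194) and -0.31 (permutation p = 0.0284), and both had an adjusted p of 0.27 over the 19 autosomes.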

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

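The tests of the 3 patterns weighed here, short losses, chromosome 2 and Trp53, were chosen only after the result was seen; the counts of other splits were planned. A tumour was singled out by Dixon's test at the 95% level. The test sets its gap to the nearest other tumour of its group against the range of the group. In 167 groups of values tested, 21 values stood out. Chance alone gives about 8.35 for independent values that were not picked for their size. The genes tested besides Trp53 were those with a focal segment in some tumour, and some values share a segment or chromosome. The 21 therefore cannot be read as an excess over chance.

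AD sarcoma 3 stood apart with 12.2% of its autosomes altered (others 0.012% to 1.04%), 2 whole-autosome changes (others 0), a mean log2 of -0.16 for chromosome 6, and, on that chromosome, -0.16 for the lowest segment of Tcrb and for that of Igk. RP sarcoma 2 stood apart with Myc at 2.22, Ccne2 at 2.04 over the whole gene, chromosome 7 at 0.21, and the chromosome 7 genes Bbc3 at 0.22 and Pnpla2 at 0.27. AD sarcoma 1 had Kit at 1.39, Pdgfra at 1.39 and Nras at 1.11, where the other AD sarcomas had at most 0.21 for Kit. AD sarcoma 5, from an animal with a sequenced ear, had its lowest Tcra/Tcrd segment at -0.83 (others 0.14 to 0.30). That segment held 2 markers. Chromosome 14 was at 0.15 in RP sarcoma 1, the lowest Tcrb segment at -0.34 in RP sarcoma 3, and the lowest Igl segment at 2.34 in RP sarcoma 5.

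Among thymic lymphomas, AD thymic lymphoma 6 had Akt1 at 4.80 and Pnpla2 at -0.66, AD thymic lymphoma 7 had Bbc3 at -0.94 over the whole gene, and RP thymic lymphoma 4 had Myc at 1.35. Of 22 tests of whether the AD minus RP difference depends on tumour type, 2 had an unadjusted permutation p under 0.05: chromosome 14 at -0.46 (p = 0.0194) and chromosome 15 at -0.31 (p = 0.0284), with an adjusted p of 0.27 for each. Outside the autosomes, the mean log2 of chromosome X lay at or beyond 0.3 either way in 14 tumours, which was not compared between groups since the sexes of the animals are not given in the sources used here.

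AD thymic lymphomas 6 and 7 had 93 and 169 losses of at most 10 markers and 50 kb, against 11 to 19 in RP thymic lymphomas. A comparison DNA shared by the AD thymic lymphomas would raise all 7, and only 3 lay above every RP thymic lymphoma, which argues against it. Of the short losses of AD thymic lymphoma 7, 25 overlapped 1 of AD thymic lymphoma 6, where 1000 random placements gave a mean of 4.27 and at most 10 (permutation p = 0.000999, the smallest these placements can give), so drop-out of the same capture targets in both libraries is a candidate explanation. The AD genotype stays open, with an exact permutation p of 0.158 for the difference of 50.3 ± 59.99 against 14.9 ± 3.53 short losses (n = 7 each), and the AD mean without AD thymic lymphomas 6 and 7 was 18. In sarcomas, AD tumours also had more short losses, 8.6 ± 3.51 against 3.4 ± 1.82 (unadjusted exact permutation p = 0.0317, n = 5 each).

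Of the 5 AD sarcomas, 4 had the gain near the end of chromosome 2 at 1.05 ± 0.12, and the animal of the remaining tumour, at 0.012, gave a sequenced ear. If that ear was its comparison DNA, a germline difference between the animals and the comparison DNA is a candidate explanation, and strain-variable zinc finger clusters are the kind of region where 1 would lie. The gain had 1 distinct pair of ends in all 4 tumours, which a gap of 1531 kb without segments before the region can also force, so a somatic gain cannot be told apart from it by the ends. Fisher's exact p for the gain in AD against RP sarcomas was 0.0476, in a region picked for its difference.

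The short segment inside Trp53 was found with the same ends in 4 thymic lymphomas, above its neighbour in 2 and below it in 2. Short segments with other ends there lay below their neighbour by 0.48 in AD thymic lymphoma 7 (at -0.20) and by 0.44 in AD sarcoma 1 (at -0.32), so the 3 AD tumours with such a segment lay below, and of the 3 RP tumours 2 lay above and 1 below. A comparison DNA shared by the RP thymic lymphomas would, on its own, put the segment on the same side in each. Its distance from the neighbour spread over 1.31 among them, from -0.45 to 0.86, which argues against such a DNA as the only source. A shared comparison DNA is not excluded, since the dose of the mutant allele can also differ between tumours. Null alleles of Trp53 commonly lack internal exons, so targets that the germline null allele lacks are a candidate source, as a ratio there would follow the dose of the mutant allele alone. Of the 24 short segments with the same ends in at least 4 tumours, among 802 distinct ones, 11 also went both ways, so such a segment is not particular to Trp53 and the explanation cannot be told apart from recurrent noise.

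Other splits of the tumours show where chance is an unlikely source of a count. For thymic lymphomas against sarcomas, 1 of 100 splits, the real one, gave as many as 8 autosomes (highest other 2). Likewise, 1 of 100 gave as many as 951 bins (highest other 344) and 1 of 100 as many as 6 listed genes (highest other 0). For receptor loci, 1 of 100 gave as many as 5 (highest other 2). Chance is therefore an unlikely source of each count, but 100 splits cannot exclude it. Of the 6 genes, 5 lie on chromosome 13 and are not independent. The count of listed genes was 0 with centring, and ran from 0 to 6 when tumours were left out in turn. For the autosomes, bins and listed genes, a difference in processing between the tumour types is not excluded, since their autosomal marker totals do not overlap (204845 to 204922 against 205073 to 205076). The lowest Tcra/Tcrd segment, at -3.52 ± 0.94 in thymic lymphomas against 0.01 ± 0.32 in sarcomas, lies far beyond the difference of -0.09 in medians between them. For AD against RP, the real counts were 0, which all 100 of 100 splits reach by construction, so these splits decide nothing. In thymic lymphomas the highest other split gave 3 autosomes, 299 bins, 0 listed genes and 6 lists, and in sarcomas 0 of each. The split with 299 bins against a real count of 0 leaves room for a structure among the thymic lymphomas that does not follow genotype, but neighbouring bins are linked and no test of such a structure was made.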

How the results depend on the processing

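The alternatives without AD thymic lymphomas 6 and 7, and the one for receptor loci against their own chromosome, were chosen only after the data were seen. Counts of autosomes, bins and listed genes in both AD against RP comparisons, and of lists in sarcomas, were 0 under every alternative and every left-out tumour. In sarcomas the counts of the exact permutation test could hardly move, since 380 bins or 4 autosomes must reach the smallest p together for any to pass. Limma has no such floor, and its smallest adjusted p for bins in sarcomas was 0.0706. Thymic lymphomas kept a higher altered share than sarcomas throughout (5.79 to 42.5 points, highest permutation p = 0.00065). At a cutoff of 0.5 the AD minus RP difference in thymic lymphomas reversed to 2.98 points for the altered share and 0.429 for whole autosomes, the interaction reversed to 2.96, 1 list differed and 0 listed genes differed between tumour types. At a cutoff of 0.2 Trp53 was lost in 1 tumour and 73 listed genes differed. With the linear cutoff the interaction was -41.0 points and 62 genes differed. On ranks the altered share in sarcomas reversed to -0.2. Joining segments gave 48.4 altered segments, and the 95% share -2.71 whole autosomes, both past the threshold. Centring left 4 autosomes, 4.4e+02 bins (153 higher and 288 lower) and 0 genes, and 5 Mb bins left 199, in part since fewer bins are tested. Without segments under 1 Mb, 3 receptor loci, not including Tcra/Tcrd, and 0 listed genes passed. Without the 4 tumours with a sequenced ear, and without AD thymic lymphomas 6 and 7, 0 listed genes passed, with fewer tumours in each. Elsewhere the cause was not tested.

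Leaving out each tumour in turn, the altered share in sarcomas ran from -0.72 (without AD sarcoma 3) to 2.33, altered segments in thymic lymphomas from 33.0 to 73.8 (exact permutation p of 0.046 without AD thymic lymphoma 1 and 0.039 without 2), whole-autosome changes from -3.17 (exact permutation p = 0.021 without RP thymic lymphoma 3) to -1.5, and listed genes between tumour types from 0 to 6, with 4 of 24 leaving a count within 1.5 times. Of 335 alternative values for 67 results on named genes, 185 stayed within 1.5 times and 150 did not. Read depth is unknown, so its part in short segments cannot be judged here.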

Other observations

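The regions in the first 3 paragraphs were chosen after their values were seen, as were the pairs of tumours named.

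AD thymic lymphomas 5 and 6, which carried the Mycn amplification, had further amplified segments on chromosome 12. In AD thymic lymphoma 6 they were at 31447098 to 32203991 (log2 2.69, with Prkar2b and Pik3cg), 33249850 to 34169994 (4.71, with Twist1 and Hdac9), 78197173 to 78837457 (4.32, with Gphn), 110666293 to 111345531 (3.95, with Hsp90aa1 and Traf3), 111961509 to 112510743 (3.91, with Kif26a) and 112598010 to 113188163 (4.80, with Akt1 and Jag2). AD thymic lymphoma 5 had 21112043 to 21417503 at 1.18 (with Adam17 and Ywhaq), 111804443 to 111872285 at 1.19 (with Xrcc3), 112495003 to 112768425 at 1.17 (with Akt1) and, among others on chromosome 9, 6168794 to 7358226 at 3.35, over the growth factor gene Pdgfd and the metalloproteinase genes Mmp13 and Mmp12.

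Other focal gains with at least 20 markers lay over known cancer genes outside the lists. RP thymic lymphoma 6 had a log2 of 1.81 at chromosome 2, 31760036 to 32248614, over the kinase gene Abl1 and the nuclear pore gene Nup214. RP sarcomas 3 and 5 shared gains on chromosome 16 over the adaptor gene Crkl, at 1.42 and 3.01, and over the kinase gene Pak2, at 1.47 and 1.17. Neither the AD sarcomas nor RP sarcomas 1, 2 and 4 had such a gain there. AD thymic lymphoma 6 had 1.85 at chromosome 18, 4168521 to 6638598, over the kinase gene Map3k8 and the transcription factor gene Zeb1, between losses of -1.14 and -1.11.

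Profiles over the bins were compared between tumours as values only. RP thymic lymphomas 2 and 7 had a Pearson correlation of 0.907 across bins, which are not independent, and the median over pairs of thymic lymphomas was 0.411 within genotype and 0.403 across genotypes. For sarcomas the medians were 0.554 and 0.517. Chromosome X had its highest mean log2, 1.88, in RP thymic lymphoma 4, and its lowest, -0.91, in AD sarcoma 2. Of the altered segments under 1 Mb, 9.77% ± 7.98 in AD thymic lymphomas (n = 7), 8.87% ± 4.64 in RP thymic lymphomas (n = 7), 13.8% ± 4.02 in AD sarcomas (n = 5) and 16.2% ± 7.40 in RP sarcomas (n = 5) overlapped 1 of 2237 genes in 15 gene families, listed before the data were examined, that vary in copy number between mouse strains.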
